A study of Rattus norvegicus with 8 samples.

How the data were processed

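Total RNA from the hearts of aged female Norway Brown rats was measured on 8 single-colour Affymetrix expression arrays. Per the labels, the rats were 18 to 22 months old and fell into 4 groups: sham surgery, ovariectomy alone, ovariectomy with estradiol from the day of surgery (early estradiol), and ovariectomy with estradiol started 9 weeks later (late estradiol). Estradiol came from a pellet of 0.5 mg under the skin that releases over 90 days. Each array held RNA pooled in equal amounts from 3 hearts, and each group had 2 such pools. A p-value therefore measures the spread between pools, in which differences between single animals are averaged, and which can be technical in part. Whether any heart entered more than 1 pool is not given in the sources used here.

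The authors deposited linear signal intensity values, 1 per probe set and array, made with MAS5 per the submitters' processing notes. MAS5 summarises the probe pairs of each probe set into a single signal. Its version, its scaling target and its detection calls are not given in the sources used here. No detection call was used, so a dim value was not separated from background except by the filter described next.

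The deposited arrays were not on a common scale. Their 2% trimmed mean signal ran from 28.2 to 137.5, and by this measure every replicate 1 array was dimmer than every replicate 2 array. By median signal, sham replicate 1 (26.48) lay slightly above sham replicate 2 (25.91). The design fixed before the data were examined had assumed arrays scaled by MAS5 and no further normalization. After the array medians were seen, and before any test was run, quantile normalization of the log2 values became the main setting, and the values without it became an alternative. Of 31099 probe sets, 57 control probe sets were left out, and the 18625 of the remaining 31042 with a mean log2 value at or above the 40th percentile were tested.

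Gene names came from the platform annotation given with the data, and were matched by Entrez number to the RefSeq gene table of the assembly GRCr8. That table was used for names only, and no coordinates are given. The annotation listed 1 gene symbol for 20826 probe sets, several for 436 and no symbol for 9780. Of the 20826, 20758 matched the RefSeq table, and 0 symbols needed an update. The kept probe sets held 13923 with 1 symbol, which stood for 10450 genes. A gene was represented by its brightest kept probe set, and probe sets with several symbols were not named.

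Differences were fitted with limma 3.58.1 in R 4.3.3, in a model of group means over all 8 arrays with an intensity trend in the prior variance. The model had 4 residual degrees of freedom, and the median residual SD was 0.395 on the log2 scale. The 6 pairwise comparisons, the mean of both estradiol groups against ovariectomy, and a moderated F test over the 4 groups were adjusted by the Benjamini-Hochberg method within each comparison, at a threshold of 0.05, two-sided. All differences are log2 differences of group means of 2 arrays each. The error given is limma's moderated standard error unless an SD or a standard error over genes is named.

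Before the data were examined, 41 gene lists (pathways, and markers of cell types or tissues that a whole heart can hold) were fixed. The 36 with at least 5 measured genes were tested with camera at its preset correlation between genes of 0.01, adjusted over the lists of a comparison. The blood cell list held 4 measured genes, the B and plasma cell, mast cell and neutrophil lists 3 each, and the list of cartilage and tissue next to the thymus 2, so these 5 lists were not tested. Camera compares a list with the other genes, and at its preset correlation it takes array differences shared by co-regulated genes for evidence. It was therefore repeated with a correlation estimated from the residuals, and fry, which tests whether the genes of a list move on balance in the same direction, was run too. Neither gave a call in any of the 7 comparisons, so that each list call below rests on the preset correlation.

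The named genes followed a rule fixed in advance. Where fewer than 5 genes passed in a direction, the 5 of smallest unadjusted p with at least a 1.5-fold difference are given as values that did not pass. Of each list described, 2 to 4 members of smallest p are named in that order of p, together with members that passed when adjusted over the list alone, and Esr1, Esr2, Gper1, Pgr, Myh6, Myh7, Nppa, Nppb, Atp2a2 and Ppargc1a are given wherever measured.

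The groups share the replicate numbers 1 and 2 in the labels. On the log2 values, the replicate 2 minus replicate 1 differences of the 4 groups correlated across genes in all 6 pairs of groups, with r from 0.28 to 0.33, so that the number was treated as a technical batch holding 1 array of each group. Genes are not independent replicates in such a correlation. The fit with this block had 3 residual degrees of freedom and a median residual SD of 0.33, and its value stands beside a result where it changed a call. Other alternatives were centring on array medians, 32 added before the log, no filter, a filter at the 60th percentile, no intensity trend, only the groups compared, a fold of at least 1.5, the mean of a gene's probe sets, and leaving out each array. Cyclic loess, no normalization, the block with 32 added, and leaving out the 2 dimmest arrays were added after the data were seen. So was an exchange of the replicate 2 arrays between the compared groups, which leaves each group with an array of both and so with no treatment difference on balance, to see what camera calls then. The sign of an exchanged value depends only on which replicate is exchanged, so it has no meaning.

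The steps were tested on simulated data for late estradiol against ovariectomy. In 5 simulations on 18625 probe sets with 200 changed in each, the fit recovered 1.78% of 2-fold, 31.2% of 4-fold and 47.6% of 8-fold changes, with 5 calls among 91738 unchanged values. With 2 arrays per group, a missed threshold therefore says little, even about changes of 8-fold. An extracellular matrix list shifted by 0.5 was called in 5 of 5 simulations. The fibroblast list, which shares collagens and other genes with it, was not counted, and none of the remaining lists was called. The simulated genes varied independently, however, and with the same spread in every group. The real ovariectomy and late estradiol groups spread more between replicates than the other groups, as given in the results. Without between-array normalization the median of all kept probe sets itself moved, by -0.31 for ovariectomy against sham, 0.18 and -0.31 for early and late estradiol against ovariectomy, -0.48 for late against early estradiol, and -0.14 and -0.62 for early and late estradiol against sham, and list medians under that setting are to be read against these shifts.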

Results

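Gene expression was compared in hearts of aged female rats after sham surgery, ovariectomy, ovariectomy with early estradiol, and ovariectomy with late estradiol, with 2 arrays per group and RNA of 3 hearts on each array. Ovariectomy removes the main source of estradiol, and the pellet replaces it either at once or after 9 weeks without it. All values are log2 signals after quantile normalization, n = 2 arrays per group.

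The arrays differed in brightness more by replicate number than by group. The 2% trimmed mean signal was 28.2 to 70.0 on the replicate 1 arrays and 104.2 to 137.5 on the replicate 2 arrays. Late estradiol replicate 1 was the dimmest array, and its ratio of 3' to 5' signal for Gapdh, a sign of RNA quality, was 2.70, against 1.26 to 1.65 on the other 7 arrays. By the same ratio for actin it did not stand apart, at 3.01, and ovariectomy replicate 2 was highest at 3.06, against 1.71 to 2.75 on the other 6 arrays. Across probe sets, replicate 2 arrays of different groups correlated at r = 0.938 to 0.960, replicate 1 arrays of different groups at r = 0.868 to 0.924, and the arrays of the same group at r = 0.863 to 0.916. The replicate 2 minus replicate 1 differences had an SD of 0.793 in sham, 0.951 after ovariectomy, 0.745 with early and 0.988 with late estradiol. The model used a common spread for all groups, so counts of small unadjusted p can also follow the spread of the groups compared. No probe set passed the threshold in any comparison (limma, Benjamini-Hochberg). The number of arrays limits the precision, and the gene groups below are described from lists fixed in advance.

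**Figure D1:**
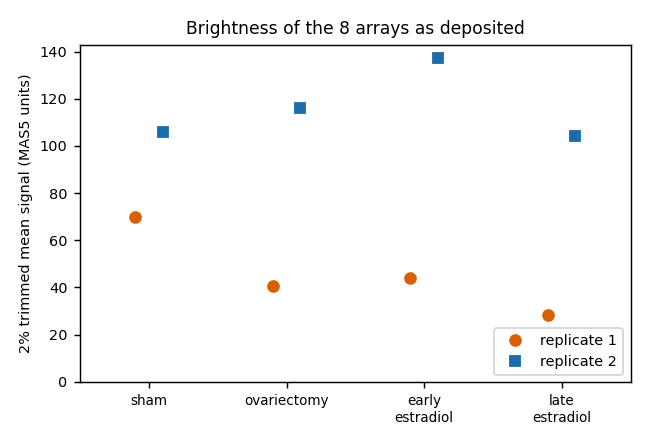
Brightness of each array as deposited. The vertical axis gives the 2% trimmed mean MAS5 signal, the horizontal axis the group, circles replicate 1 and squares replicate 2; each replicate 2 array, at 104.2 or more, lay above each replicate 1 array, at 70.0 or less.

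The comparison of ovariectomy with sham surgery asked what loss of the ovaries does to the aged heart. Genes of macrophages, of fibroblasts and of the extracellular matrix lay higher after ovariectomy, and genes of the circadian clock lay lower. The macrophage and monocyte list rose by a median of 0.56, with 20 of 20 measured genes higher and 11 higher in both replicates (camera adjusted p = 8.7e-08, adjusted p = 0.64 with an estimated correlation). Its genes of smallest p were Fcer1g, the signalling chain of Fc receptors, at 1.33 ± 0.39, and Gpnmb, a glycoprotein of lipid-laden macrophages, at 2.10 ± 0.84. Without ovariectomy replicate 1, Gpnmb stood at 3.86 and passed (limma adjusted p = 0.0367). The list median was 0.21 in replicate 1 and 1.47 in replicate 2. The extracellular matrix and fibrosis list rose by a median of 0.16, with 39 of 54 genes higher (camera adjusted p = 6.43e-05, adjusted p = 0.59 with an estimated correlation), but the median was -0.07 in replicate 1 and 0.39 in replicate 2. The fibroblast list rose by 0.15, with 13 of 16 genes higher (camera adjusted p = 7.88e-05, adjusted p = 0.59 with an estimated correlation). It shares Col1a1, Col1a2, Col3a1 and other genes with the matrix list, so calls of both lists are not independent in any comparison. Col3a1 and Col1a1, the fibril-forming collagens of types III and I, stood at 0.79 ± 0.19 and 1.06 ± 0.29, Postn, a matrix protein of activated fibroblasts, at 0.96 ± 0.41, and Timp2, an inhibitor of matrix metalloproteinases, at 0.42 ± 0.17.

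The list of MHC class II and antigen presentation, called the MHC class II list below, also holds class I genes and was not split. It too rose after ovariectomy, by a median of 0.17 with 14 of 21 genes higher (camera adjusted p = 0.00107, adjusted p = 0.59 with an estimated correlation). The class II genes RT1-Db1, RT1-DMa, RT1-Ba and RT1-Da stood at 1.25 ± 0.39, 1.08 ± 0.41, 0.97 ± 0.35 and 0.92 ± 0.40, and the list median was -0.02 in replicate 1 and 0.41 in replicate 2. The hypertrophic and fetal programme list rose by 0.09, with 14 of 19 genes higher (camera adjusted p = 0.0459, adjusted p = 0.61 with an estimated correlation), led by Acta1, the skeletal actin that the fetal heart expresses, at 0.76 ± 0.22, and Acta2, smooth muscle actin, at 0.56 ± 0.34. Without between-array normalization the medians of the matrix, fibroblast, MHC class II and hypertrophic lists were -0.14, -0.12, -0.14 and -0.13, where that of all probe sets was -0.31. The circadian clock list fell, with a median of -0.27, 16 of 19 genes lower and 10 of them lower in both replicates (camera adjusted p = 0.00107, adjusted p = 0.51 with an estimated correlation). Its medians were -0.38 in replicate 1 and -0.33 in replicate 2. Wee1, a cell cycle kinase under clock control, stood at -1.57 ± 0.46. Dbp and Tef, transcription factors of the clock's output, stood at -0.62 ± 0.25 and -0.77 ± 0.51, and Cry1, a repressor within the clock, at -0.67 ± 0.45. In this comparison, 2 genes of the fibroblast list (Col3a1 and Col1a1) passed when adjusted over the list alone, against 0 over all probe sets, and 0 genes of the other 5 called lists did.

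Single genes of smallest p after ovariectomy that did not pass were Col3a1, Col1a1, Tubb6 at 1.87 ± 0.45, Lilrb4, an inhibitory receptor of myeloid cells, at 2.90 ± 0.74, and Pf4, platelet factor 4, at 1.03 ± 0.27. Those lower were Sinhcaf, a subunit of the SIN3-HDAC complex, at -2.83 ± 0.55, Fgd6 at -2.02 ± 0.54, Phf14 at -0.90 ± 0.24, Mpp7 at -1.08 ± 0.30, and Wee1. Sinhcaf was dim, with mean log2 signals of 5.54 in sham and 2.71 after ovariectomy. The cardiac myosin heavy chains Myh6 and Myh7 differed by -0.09 ± 0.16 and 0.07 ± 0.14. Nppb and Nppa, the B-type and atrial natriuretic peptides, differed by -0.08 ± 0.17 and 0.70 ± 0.67. Atp2a2, the calcium pump of the sarcoplasmic reticulum, differed by -0.01 ± 0.14, and 2 of its 4 other probe sets went the other way, as 2 or 3 did in every pairwise comparison. The other probe sets of Myh6 for early estradiol against ovariectomy, and of Myh7 for late estradiol against ovariectomy and against early estradiol, also went the other way. Ppargc1a, a coactivator of mitochondrial biogenesis, differed by -0.16 ± 0.28. Esr1, Esr2 and Pgr, the classical estrogen and progesterone receptors, did not pass the filter on dim probe sets. Gper1, the membrane estrogen receptor, was near the floor of the array and differed by -0.21 ± 1.19. Of 18625 probe sets, 0 passed in limma and 274 had an unadjusted p under 0.05, where chance gives 931. The fit with the replicate block also called 0, with 573 under 0.05. Without ovariectomy replicate 2 the macrophage list had a median of 0.05 (camera adjusted p = 0.999), and the matrix, fibroblast, MHC class II and hypertrophic lists had medians of 0.04, 0.10, -0.04 and 0.08 (adjusted p = 0.923 each). Without ovariectomy replicate 1 the clock list had an adjusted p of 0.0956, without sham replicate 2 the matrix and hypertrophic lists had 0.05 and 0.172, and without sham replicate 1 the hypertrophic list had 0.0859.

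The sizes of the ovariectomy list differences depended on single arrays too. With 1 array left out, the macrophage median ranged from 0.05 without ovariectomy replicate 2 to 1.69 without ovariectomy replicate 1, and between the same 2 settings the matrix median ranged from 0.04 to 0.33, the fibroblast median from 0.10 to 0.39 and the MHC class II median from -0.04 to 0.37. The clock median ranged from -0.52 without sham replicate 1 to -0.07 without ovariectomy replicate 1, and was also -0.07 without the 2 dimmest arrays, where the clock call ended (adjusted p = 0.126). The hypertrophic median ranged from 0.04 without sham replicate 2 to 0.16 without ovariectomy replicate 1, and its call ended with no filter (adjusted p = 0.143), no intensity trend (0.183) and the mean of a gene's probe sets (0.0603). Without between-array normalization the hypertrophic, MHC class II and fibroblast calls ended (0.391 each). With the replicate 2 arrays of ovariectomy and sham exchanged, macrophage and matrix genes were called too, at medians of -0.54 and -0.21 (camera adjusted p = 0.00408 and 0.00339).

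The comparison of early estradiol with ovariectomy asked what replacement from the time of surgery does. Genes of the MHC class II list and of the interferon response were lower with early estradiol. Genes of the complement system, immediate early genes and mesothelial genes were higher. The MHC class II list fell, with a median of -0.34 and 17 of 21 genes lower, 11 of them in both replicates (camera adjusted p = 0.000325, adjusted p = 0.53 with an estimated correlation). The list median was -0.06 in replicate 1 and -0.46 in replicate 2. RT1-Ba, RT1-DMa and RT1-Bb stood at -0.89 ± 0.35, -0.94 ± 0.41 and -0.88 ± 0.44. The interferon response list fell, with a median of -0.19 and 27 of 37 genes lower (camera adjusted p = 0.0168, adjusted p = 0.53 with an estimated correlation). Its leading genes went both ways, with Cxcl11, an interferon-induced chemokine, at -0.57 ± 0.23, Usp18, a brake on interferon signalling, at -0.62 ± 0.28, and Isg20, an interferon-induced exonuclease, at 2.28 ± 1.04. Without between-array normalization the median was 0.01, where that of all probe sets was 0.18.

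The complement list rose with early estradiol, with a median of 0.38 and 11 of 14 genes higher (camera adjusted p = 0.00348, adjusted p = 0.53 with an estimated correlation). C3, the central complement component, stood at 2.17 ± 0.69, Serping1, the inhibitor of the first component, at 0.53 ± 0.21, and C1qb, a chain of that component, at 0.89 ± 0.38. The list median was 0.76 in replicate 1 and 0.12 in replicate 2. The immediate early genes, which respond within minutes to stimulation, rose by a median of 0.24 with 22 of 29 higher (camera adjusted p = 0.00348, adjusted p = 0.53 with an estimated correlation). The transcription factors Egr1, Klf10, Fos and Nr4a1 stood at 1.08 ± 0.36, 0.92 ± 0.32, 1.28 ± 0.46 and 1.35 ± 0.58, but at 0.34, 0.62, 0.34 and 0.03 in replicate 2. The mesothelial and epicardial list rose by a median of 0.63 with 7 of 8 genes higher (camera adjusted p = 0.0358, adjusted p = 0.53 with an estimated correlation). Beside C3, which is also on that list, its genes of smallest p were Aldh1a2, an enzyme of retinoic acid synthesis, at 0.66 ± 0.61, Lrrn4, a membrane protein of mesothelium, at 0.81 ± 0.79, and Wt1, a transcription factor of the epicardium, at 0.32 ± 0.32. None of the genes of the 5 called lists passed when adjusted over the list alone, and 0 passed over all probe sets.

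Of single genes that did not pass, Pla2g2a, a secreted phospholipase A2 of inflammation, was higher by 1.21 ± 0.26 with early estradiol, S100a9, a calcium-binding protein of neutrophils and monocytes, by 2.38 ± 0.70, Tox, a nuclear protein of T cell development, by 1.43 ± 0.41, and Sinhcaf by 2.25 ± 0.55. Sppl2a, an intramembrane protease, was higher by 0.98 ± 0.27, with 1 of its 3 other probe sets going the other way. Ampd2, an AMP deaminase, stood at -1.74 ± 0.44, Gngt2 at -0.93 ± 0.25, Pde6g at -2.75 ± 0.76, Dxo at -3.07 ± 0.87, and LOC100909739, a gene without a name, at -1.04 ± 0.27. Myh6, Myh7, Nppb and Atp2a2 differed by -0.03 ± 0.16, 0.10 ± 0.14, -0.02 ± 0.17 and 0.01 ± 0.14, Nppa by 0.41 ± 0.67, Ppargc1a by 0.13 ± 0.28 and Gper1 by 0.09 ± 1.19. In limma 0 of 18625 probe sets passed and 318 had an unadjusted p under 0.05, against 0 and 685 with the replicate block. Without early estradiol replicate 1, the complement, immediate early and mesothelial lists each had a camera adjusted p of 0.246 and the interferon list 0.253. Without ovariectomy replicate 2 the MHC class II and interferon lists had 0.441, the mesothelial list 0.321 and the immediate early list 0.0825. The complement list had 0.187 without ovariectomy replicate 1, and the MHC class II list 0.0748 without early estradiol replicate 2.

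With 1 array left out, the MHC class II median for early estradiol against ovariectomy ranged from -0.60 without ovariectomy replicate 1 to -0.15 without ovariectomy replicate 2. The interferon median ranged from -0.31 without ovariectomy replicate 1 to -0.10 without early estradiol replicate 1, the complement median from 0.11 without ovariectomy replicate 1 to 0.57 without ovariectomy replicate 2, and the mesothelial median was 0.37 without ovariectomy replicate 2. With 32 added before the log, the mesothelial and immediate early medians were 0.24 and 0.15. The interferon call ended with no filter (adjusted p = 0.0688) and without between-array normalization (0.126), and the complement call without the 2 dimmest arrays, at a median of 0.01 (0.217). With the replicate 2 arrays of early estradiol and ovariectomy exchanged, the complement list (median 0.34, camera adjusted p = 0.00687) and the MHC class II list (0.13, 0.00457) were called too. Macrophage, fibroblast and matrix genes, not called between the real groups, were then called as well, at medians of 1.05, 0.30 and 0.17 (3.5e-14, 0.000249 and 3.77e-05).

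The comparison of late estradiol with ovariectomy asked what the same pellet does when started 9 weeks after surgery. Collagens and other genes of the extracellular matrix were lower with late estradiol, and fibroblast and macrophage genes were lower as well. The extracellular matrix and fibrosis list fell, with a median of -0.56 and 45 of 54 genes lower, 35 of them in both replicates (camera adjusted p = 1.11e-14, adjusted p = 0.49 with an estimated correlation). Its medians were -0.51 in replicate 1 and -0.57 in replicate 2, but different arrays stood out in each. Relative to sham, the matrix means were -0.10 after ovariectomy and -0.59 on the dim late estradiol array in replicate 1, and 0.53 and -0.21 in replicate 2, where the ovariectomy array was high. Adjusted over the list alone, 8 genes passed, all lower, against 0 over all probe sets. These were Col3a1 at -1.72 ± 0.19, Col1a1 at -1.71 ± 0.29, Col15a1 at -1.07 ± 0.23, Loxl1, a cross-linking enzyme of elastic fibres, at -1.26 ± 0.27, Timp2 at -0.76, Col1a2 at -1.19 ± 0.34, Mmp2, a gelatinase, at -0.74 and Col6a3 at -1.16. Col3a1 was 3.29-fold lower, at a mean log2 signal of 8.90 against 10.62. Its limma adjusted p was 0.0674, and 0.0177 with the replicate block, where it was the only probe set called in any comparison.

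The fibroblast list, part of whose genes are also on the matrix list, fell with late estradiol, with a median of -0.41 and 15 of 16 genes lower (camera adjusted p = 7.81e-08, adjusted p = 0.49 with an estimated correlation). Adjusted over the list alone 4 of its genes passed, Col3a1, Col1a1, Col1a2 and Mfap5, a microfibril protein at -0.91 ± 0.26. The macrophage list fell, with a median of -0.94 and 18 of 20 genes lower (camera adjusted p = 2.24e-06, adjusted p = 0.82 with an estimated correlation), led by Fcer1g at -1.21 ± 0.39, Gpnmb at -2.41 ± 0.84 and Cybb, a subunit of the phagocyte NADPH oxidase, at -1.01 ± 0.42. The cell cycle list fell, with a median of -0.49 and 15 of 19 genes lower (camera adjusted p = 0.00573, adjusted p = 0.49 with an estimated correlation). Its genes of smallest p were dim, with Top2a, a DNA topoisomerase, at -2.06 ± 0.87 and a mean log2 signal of 2.52 with late estradiol. Nusap1, a protein of the mitotic spindle, stood at -1.02 ± 0.43, and its other probe set went the other way. The antioxidant list fell, with a median of -0.15 and 30 of 42 genes lower (camera adjusted p = 0.037, adjusted p = 0.82 with an estimated correlation). Beside Cybb, which makes superoxide, it was led by Gpx1, a glutathione peroxidase, at -0.33 ± 0.14. The ribosomal protein list rose by a median of 0.09, with 36 of 42 genes higher (camera adjusted p = 0.0108, adjusted p = 0.82 with an estimated correlation), led by Rpl21 at 0.43 ± 0.15 and Rpl39 at 1.67 ± 0.93. Its median was -0.14 without between-array normalization, where that of all probe sets was -0.31. Of these 4 lists, 0 genes passed when adjusted over the list alone.

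Single genes of smallest p, none of which passed, included Mfap4, a microfibril-associated protein, at -1.53 ± 0.31 and Fam234a at -1.19 ± 0.25, beside Col3a1, Col1a1 and Col15a1. Higher were Sinhcaf at 3.04 ± 0.55, Amd1, an enzyme of polyamine synthesis, at 0.88 ± 0.18, Tox at 1.59 ± 0.41, Perp, a desmosomal protein, at 0.66 ± 0.17, and Bex1 at 1.01 ± 0.27. Ppargc1a stood at 0.66 ± 0.28, Nppb at 0.31 ± 0.17 and Nppa at 0.59 ± 0.67, and Myh6, Myh7 and Atp2a2 at -0.06 ± 0.16, 0.10 ± 0.14 and -0.04 ± 0.14. Gper1 stood at -0.56 ± 1.19. In limma 0 of 18625 probe sets passed and 812 had an unadjusted p under 0.05, against 1 and 1495 with the replicate block. Without late estradiol replicate 2, which left the dimmest array to stand for its group, 65 probe sets passed, and without ovariectomy replicate 1 Gpnmb stood at -4.17 and passed (limma adjusted p = 0.0276). The matrix and fibroblast calls held when any array was left out. Without ovariectomy replicate 2 the macrophage, cell cycle and antioxidant lists had camera adjusted p values of 0.763, 0.763 and 0.774, and without late estradiol replicate 1 the macrophage and antioxidant lists had 0.108 and 0.591. Without late estradiol replicate 2 the cell cycle and ribosomal lists had 0.271 and 0.739, and without ovariectomy replicate 1 the ribosomal list had 0.787.

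With 1 array left out, the matrix median for late estradiol against ovariectomy ranged from -0.73 without late estradiol replicate 2 to -0.36 without late estradiol replicate 1, and the fibroblast median from -0.84 without late estradiol replicate 2 to -0.19 without ovariectomy replicate 2. The macrophage median ranged from -1.82 without ovariectomy replicate 1 to -0.23 without ovariectomy replicate 2, and was -0.57 with 32 added before the log. The cell cycle median was -0.17 without ovariectomy replicate 2, -0.26 with 32 added before the log, and -0.16 with the filter at the 60th percentile, which ended its call (adjusted p = 0.113). The antioxidant median ranged from -0.25 without ovariectomy replicate 1 to -0.07 without late estradiol replicate 1. The antioxidant call also ended with median centring (adjusted p = 0.05), no filter (0.0568), no intensity trend (0.125), the mean of a gene's probe sets (0.0858) and no normalization (0.63). The ribosomal median ranged from -0.01 without late estradiol replicate 2 to 0.19 without late estradiol replicate 1, and its call also ended with no intensity trend (0.119), no normalization (0.287) and without the 2 dimmest arrays (0.0799). With the replicate 2 arrays of late estradiol and ovariectomy exchanged, none of these 6 lists was called, while camera called the TCA cycle, fatty acid oxidation and hypertrophic lists, 3 lists that the real groups did not give.

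**Figure D2:**
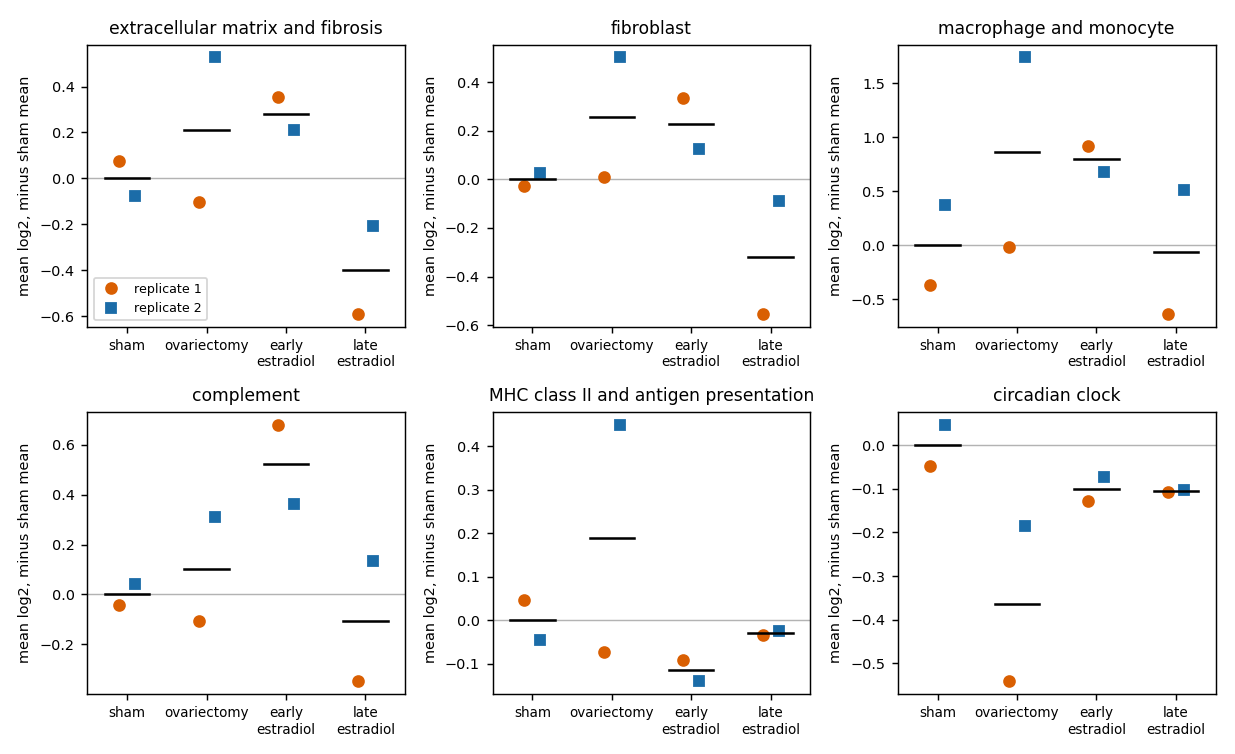
Mean log2 signal of the measured genes of 6 lists on each array, minus the mean of the 2 sham arrays. Circles stand for replicate 1, squares for replicate 2 and bars for group means; the extracellular matrix values were -0.59 and -0.21 with late estradiol and 0.35 and 0.21 with early estradiol, and the macrophage values of the ovariectomy group were -0.02 and 1.74.

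The comparison of late with early estradiol asked whether the time at which estradiol was started matters. The labels used here give neither the length of exposure nor the time from surgery to harvest. A later start can therefore also mean a shorter exposure or a longer time since surgery. These were not separated from the start time. Matrix, fibroblast, complement and macrophage genes were lower with late than with early estradiol. The extracellular matrix and fibrosis list fell, with a median of -0.52, 47 of 54 genes lower and 42 of them lower in both replicates (camera adjusted p = 2.09e-16, adjusted p = 0.52 with an estimated correlation). Adjusted over the list alone 5 of its genes passed, against 0 over all probe sets: Col3a1 at -1.08 ± 0.19, Col1a1 at -1.45 ± 0.29, Col1a2 at -1.26 ± 0.34, Loxl1 at -1.08 ± 0.27, and Col14a1, a collagen associated with fibrils, at -0.93 ± 0.22, whose other probe set went the other way. The fibroblast list fell, with a median of -0.43 and 14 of 16 genes lower (camera adjusted p = 3.14e-07, adjusted p = 0.52 with an estimated correlation), and Col3a1, Col1a1, Col1a2 and Mfap5 (-0.91 ± 0.26) passed when adjusted over the list alone, 4 genes in all. Its median was -0.71 in replicate 1 and -0.07 in replicate 2.

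The complement list fell, with a median of -0.68 and 13 of 14 genes lower (camera adjusted p = 1.3e-06, adjusted p = 0.52 with an estimated correlation). Adjusted over the list alone 2 of its genes passed, Serping1 at -0.87 ± 0.21 and Clu, a chaperone that inhibits complement, at -0.56 ± 0.16, whose other probe set went the other way, and C3 stood at -1.77 ± 0.69. The macrophage list fell, with a median of -0.75 and 20 of 20 genes lower, 14 of them in both replicates (camera adjusted p = 1.02e-06, adjusted p = 0.52 with an estimated correlation). Its genes of smallest p were Lyve1, a receptor of resident macrophages, at -1.03 ± 0.39 and Cybb at -1.05 ± 0.42. Medians of the complement and macrophage lists were -1.22 and -1.41 in replicate 1, which held the dim late estradiol array, and -0.22 and -0.26 in replicate 2.

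The glycolysis and glucose uptake list fell, with a median of -0.20 and 19 of 25 genes lower (camera adjusted p = 0.0157, adjusted p = 0.52 with an estimated correlation), led by Ldha, lactate dehydrogenase A, at -0.40 ± 0.13, Pygm, the muscle glycogen phosphorylase, at -0.48 ± 0.16, and Gys1, glycogen synthase, at -0.77 ± 0.31. The TCA cycle list fell, with a median of -0.10 and 14 of 21 genes lower (camera adjusted p = 0.0424, adjusted p = 0.52 with an estimated correlation), led by Ogdh and Idh3a, subunits of its dehydrogenases, at -0.51 ± 0.15 and -0.52 ± 0.19, and the replicate block ended this call (adjusted p = 0.0588). The antioxidant list fell, with a median of -0.20 and 29 of 42 genes lower (camera adjusted p = 0.0215, adjusted p = 0.52 with an estimated correlation), led by Cybb and by Gsta1, a glutathione transferase, at -0.73 ± 0.33. The ribosomal protein list rose by a median of 0.06 with 31 of 42 genes higher (camera adjusted p = 0.0424, adjusted p = 0.70 with an estimated correlation), led by Rpl21 at 0.33 ± 0.15 and Rpl35 at 0.30 ± 0.14. Its median was -0.25 without between-array normalization, where that of all probe sets was -0.48. Of these and the macrophage list, 0 genes passed when adjusted over the list alone.

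Single genes that did not pass were led by Col3a1, Tpgs1 at -3.84 ± 0.74, Col1a1, C13h1orf74 at -2.87 ± 0.57 and Serpinf1, an inhibitor of blood vessel growth, at -1.32 ± 0.27. Higher with late estradiol were Tma7 at 0.79 ± 0.20, LOC100909739 at 1.05 ± 0.27, Tle6 at 3.001 ± 0.79, Adgrf5 at 0.70 ± 0.19 and Eeig2 at 0.76 ± 0.21. Tpgs1 and Tle6 were near the floor in the lower group, at mean log2 signals of 1.29 and 2.22. Ppargc1a stood at 0.53 ± 0.28, with its other probe set going the other way, and Nppb at 0.33 ± 0.17. Values were near 0 for Myh6, Myh7, Nppa and Atp2a2, at -0.03 ± 0.16, 0.00 ± 0.14, 0.18 ± 0.67 and -0.05 ± 0.14, and Gper1 stood at -0.64 ± 1.19. In limma 0 of 18625 probe sets passed and 721 had an unadjusted p under 0.05, against 0 and 1451 with the replicate block, while 100 passed without late estradiol replicate 2. Among these were Lyve1 at -1.75 (limma adjusted p = 0.0302) and C13h1orf74 at -3.51 (0.0436). The matrix, fibroblast, complement and macrophage calls held when any array was left out, but the same 4 lists were also called with the replicate 2 arrays of late and early estradiol exchanged. Their medians were then -0.19, -0.30, -0.40 and -0.56 (camera adjusted p = 0.0184, 0.00402, 0.00157 and 0.000107). Without late estradiol replicate 2 the glycolysis, TCA and ribosomal lists had camera adjusted p values of 0.212, 0.186 and 0.850, and without late estradiol replicate 1 the TCA and antioxidant lists had 0.0983 and 0.244. Without early estradiol replicate 1 the TCA and ribosomal lists had 0.210 and 0.517, and without early estradiol replicate 2 the glycolysis and antioxidant lists had 0.128 and 0.0532. The TCA list had 0.0509 without ovariectomy replicate 1.

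The sizes of the differences between late and early estradiol depended on the dimmest array, late estradiol replicate 1. Without it the matrix, fibroblast, complement and macrophage medians were -0.33, -0.17, -0.29 and -0.30, and without late estradiol replicate 2 they were -0.65, -0.61, -0.90 and -1.12. The antioxidant and TCA medians were -0.05 each without late estradiol replicate 1, and the glycolysis median ranged from -0.33 without early estradiol replicate 1 to -0.09 without early estradiol replicate 2. The ribosomal median ranged from -0.02 without late estradiol replicate 2 to 0.16 without late estradiol replicate 1. Median centring ended the TCA and glycolysis calls (adjusted p = 0.361 and 0.101), no intensity trend the TCA, glycolysis, antioxidant and ribosomal calls (0.147, 0.0827, 0.0827 and 0.158), and no filter the ribosomal call (0.101). No normalization ended the same 4 calls (0.566, 0.327, 0.288 and 0.158), cyclic loess the TCA call (0.133), and leaving out the 2 dimmest arrays the TCA and antioxidant calls (0.12 and 0.275). Oxidative phosphorylation and fatty acid oxidation genes were not called between late and early estradiol (camera adjusted p = 0.243 and 0.101).

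**Figure D3:**
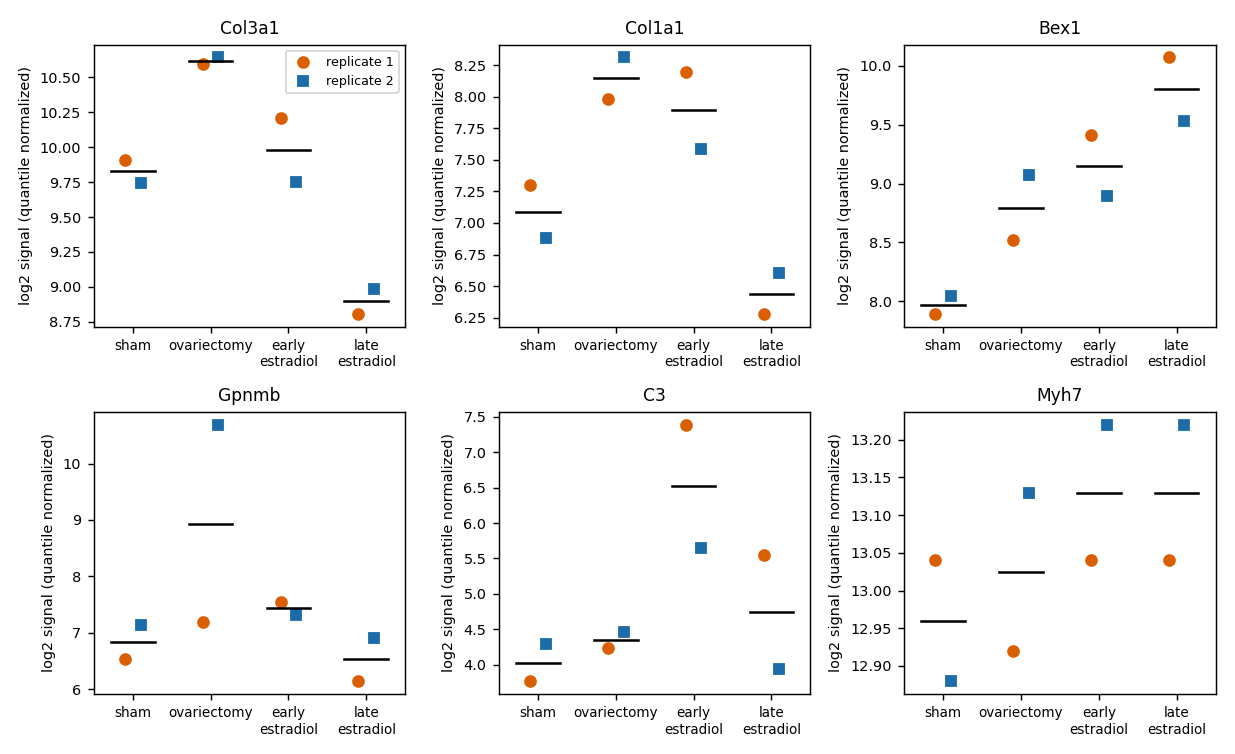
Log2 signal of Col3a1, Col1a1, Bex1, Gpnmb, C3 and Myh7 on each array after quantile normalization, with circles for replicate 1, squares for replicate 2 and bars for group means. Col3a1 had group means of 9.83 in sham, 10.62 after ovariectomy, 9.98 with early and 8.90 with late estradiol, and Gpnmb stood at 10.69 on ovariectomy replicate 2 and at 7.18 on replicate 1.

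The comparison of early estradiol with sham surgery asked whether replacement from the time of surgery leaves the heart like that of an intact animal. Genes of macrophages, complement, matrix and several other cell types of the heart lay higher with early estradiol, and genes of oxidative phosphorylation lay slightly lower. The macrophage list rose by a median of 0.67, with 20 of 20 genes higher in both replicates (camera adjusted p = 1.19e-09, adjusted p = 0.40 with an estimated correlation). It was led by Lyz2, lysozyme, at 1.13 ± 0.53 and Aif1, a calcium-binding protein of macrophages, at 2.65 ± 1.43, whose other probe set went the other way. The complement list rose by 0.49 with 13 of 14 genes higher (camera adjusted p = 2.03e-07, adjusted p = 0.39 with an estimated correlation), with C3 at 2.49 ± 0.69 and Serping1 at 0.52 ± 0.21. The matrix list rose by 0.18 with 38 of 54 genes higher (camera adjusted p = 7.18e-06, adjusted p = 0.40 with an estimated correlation), with Col1a1 at 0.80 ± 0.29 and Postn at 1.07 ± 0.41. The fibroblast list rose by 0.17 with 15 of 16 higher (camera adjusted p = 0.000646, adjusted p = 0.40 with an estimated correlation), with Col1a1 and then Fbln1, fibulin 1, at 0.58 ± 0.33. The inflammatory cytokine and NF-kB list rose by 0.16 with 24 of 37 genes higher (camera adjusted p = 0.00494, adjusted p = 0.40 with an estimated correlation), led by S100a9 and S100a8, partners in calprotectin, at 2.61 ± 0.70 and 1.80 ± 0.67.

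The mesothelial and epicardial list rose by 0.41 with 7 of 8 genes higher (camera adjusted p = 0.00223, adjusted p = 0.32 with an estimated correlation), with Upk1b, a uroplakin of mesothelium, at 1.59 ± 0.78. C3, its gene of smallest p, passed when adjusted over the list alone, the only such gene of the 14 called lists, against 0 over all probe sets. The atrial cardiomyocyte list rose by 0.25 with 8 of 12 genes higher (camera adjusted p = 0.00448, adjusted p = 0.40 with an estimated correlation), with Myl4, the atrial light chain, at 1.91 ± 0.52 and Nr2f2, a transcription factor of atrial identity, at 0.59 ± 0.30, whose other probe set went the other way. The hypertrophic and fetal programme list rose by 0.26 with 14 of 19 genes higher (camera adjusted p = 0.00192, adjusted p = 0.40 with an estimated correlation), with Nppa at 1.12 ± 0.67 and Fhl1, a stretch-responsive sarcomere protein, at 0.26 ± 0.17. Nppa stood at 2.21 in replicate 1 and 0.02 in replicate 2. The smooth muscle and pericyte list rose by 0.39 with 10 of 13 genes higher (camera adjusted p = 0.00472, adjusted p = 0.32 with an estimated correlation), with Pdgfrb, a receptor of pericytes, at 0.66 ± 0.39 and Mylk, myosin light chain kinase, at 0.39 ± 0.23. The endothelial list rose by 0.10 with 10 of 15 genes higher (camera adjusted p = 0.0368, adjusted p = 0.40 with an estimated correlation), with Plvap, a protein of fenestrae, at 2.40 ± 0.66 and Vwf, von Willebrand factor, at 0.64 ± 0.27. The immediate early list rose by 0.18 with 20 of 29 genes higher (camera adjusted p = 0.0382, adjusted p = 0.40 with an estimated correlation), with Egr1 at 0.66 ± 0.36 and Ier3 at 0.38 ± 0.26. The ribosomal list rose by 0.05 with 31 of 42 genes higher (camera adjusted p = 0.019, adjusted p = 0.55 with an estimated correlation), with Rpl21 at 0.30 ± 0.15 and Rps28 at 0.45 ± 0.23. Without between-array normalization the medians of the endothelial and ribosomal lists were -0.05 and -0.04, where that of all probe sets was -0.14. The oxidative phosphorylation list fell, with a median of -0.07 and 63 of 74 genes lower (camera adjusted p = 2.83e-05, adjusted p = 0.32 with an estimated correlation), with Cox7a1, a subunit of cytochrome c oxidase, at -0.50 ± 0.23. Ndufa9, of complex I, stood at -0.25 ± 0.14, and its other probe set went the other way. Relative to sham the oxidative phosphorylation mean was -0.09 with early estradiol, -0.05 after ovariectomy and -0.06 with late estradiol. The list was not called for early estradiol against ovariectomy (camera adjusted p = 0.183). The endoplasmic reticulum stress list fell, with a median of -0.09 and 22 of 29 genes lower (camera adjusted p = 0.0412, adjusted p = 0.40 with an estimated correlation), with Herpud1, a component of protein degradation at the reticulum, at -0.59 ± 0.24 and Eif2ak3, the stress sensor PERK, at -1.19 ± 0.66. The replicate block ended this call (adjusted p = 0.0524).

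Single genes of smallest p that did not pass were Pla2g2a at 1.34 ± 0.26, Bex1 at 1.18 ± 0.27, S100a9, Plvap and Myl4, and, lower, Phf14 at -0.90 ± 0.24, Ampd2 at -1.55 ± 0.44, Iqsec3 at -2.04 ± 0.61, Tle6 at -2.56 ± 0.79 and Itih1 at -2.31 ± 0.76. Myh6, Myh7, Nppb, Atp2a2 and Ppargc1a differed by -0.12 ± 0.16, 0.17 ± 0.14, -0.10 ± 0.17, 0.00 ± 0.14 and -0.03 ± 0.28, and the other probe set of Ppargc1a went the other way. Gper1 differed by -0.13 ± 1.19. In limma 0 of 18625 probe sets passed and 144 had an unadjusted p under 0.05, against 0 and 303 with the replicate block. The macrophage and complement calls held when any array was left out. Without early estradiol replicate 1 the atrial, hypertrophic, fibroblast, inflammatory, matrix and mesothelial lists had camera adjusted p values of 0.314, 0.298, 0.298, 0.288, 0.0625 and 0.0647, and the endoplasmic reticulum stress and immediate early lists 0.471 and 0.735. Without sham replicate 2 the inflammatory, immediate early, endothelial, smooth muscle, matrix and hypertrophic lists had 0.536, 0.38, 0.148, 0.129, 0.0789 and 0.0694. Without early estradiol replicate 2 the endothelial, ribosomal and smooth muscle lists had 0.847, 0.493 and 0.0785, and without sham replicate 1 the ribosomal, endoplasmic reticulum stress and endothelial lists had 0.857, 0.693 and 0.0783. Even leaving out an array of the ovariectomy group, which is not compared here, ended calls, with 0.0676, 0.0715 and 0.0715 for the endoplasmic reticulum stress, immediate early and ribosomal lists without its replicate 1 and 0.0582 for the endoplasmic reticulum stress list without its replicate 2.

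Other settings ended further calls of early estradiol against sham. Median centring ended the oxidative phosphorylation, ribosomal, endoplasmic reticulum stress and immediate early calls (adjusted p = 0.313, 0.128, 0.072 and 0.0712), and cyclic loess the oxidative phosphorylation call (0.37). No filter ended the ribosomal, immediate early, endothelial and endoplasmic reticulum stress calls (0.12, 0.115, 0.0519 and 0.0519), and no intensity trend the same 4 calls (0.179, 0.0501, 0.0501 and 0.121). The filter at the 60th percentile ended the endothelial and endoplasmic reticulum stress calls (0.149 and 0.0524), only the groups compared the immediate early and ribosomal calls (0.0541 each), and the mean of a gene's probe sets the atrial and immediate early calls (0.0931 and 0.0772). Without normalization the oxidative phosphorylation, ribosomal, immediate early, endoplasmic reticulum stress, smooth muscle, fibroblast and endothelial calls ended (0.57, 0.633, 0.462, 0.316, 0.225, 0.176 and 0.0701), and without the 2 dimmest arrays the immediate early and ribosomal calls (0.0668 each). With 32 added before the log, the mesothelial and immediate early medians were 0.22 and 0.11.

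With 1 array left out, the macrophage median for early estradiol against sham ranged from 0.37 to 0.83 (without sham replicate 1 and 2) and the complement median was 0.33 without early estradiol replicate 1. Without sham replicate 2 the matrix, inflammatory, immediate early, smooth muscle and hypertrophic medians were 0.10, 0.10, 0.02, 0.09 and 0.13, and without early estradiol replicate 1 the atrial, fibroblast, hypertrophic and endoplasmic reticulum stress medians were 0.11, 0.08, 0.12 and -0.02. The endothelial median turned to -0.06 without early estradiol replicate 2, the ribosomal median to -0.03 without sham replicate 1, and the mesothelial median ranged from 0.34 without early estradiol replicate 1 to 0.68 without sham replicate 1. With the replicate 2 arrays of early estradiol and sham exchanged, macrophage and endoplasmic reticulum stress genes were called too, at medians of 0.33 and -0.15 (camera adjusted p = 0.0112 and 0.0413).

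The comparison of late estradiol with sham surgery asked the same for the delayed start. Matrix genes lay below the sham level with late estradiol, as did genes of the TCA cycle and of fatty acid oxidation. The extracellular matrix list fell, with a median of -0.23 and 45 of 54 genes lower, 28 of them in both replicates (camera adjusted p = 2.05e-06, adjusted p = 0.62 with an estimated correlation). Its median was -0.47 in replicate 1, which held the dim late estradiol array with the high Gapdh ratio, and -0.12 in replicate 2. Adjusted over the list alone 2 of its genes passed, Col3a1 at -0.93 ± 0.19 and Loxl1 at -1.21 ± 0.27, and Mmp2 stood at -0.67 ± 0.21. The fibroblast list fell, with a median of -0.30 and 11 of 16 genes lower (camera adjusted p = 0.00705, adjusted p = 0.62 with an estimated correlation), with Col1a2 at -0.82 ± 0.34 and Mfap5 at -0.63 ± 0.26, and Col3a1 alone, 1 gene, passed when adjusted over the list alone. The TCA cycle list fell, with a median of -0.20 and 20 of 21 genes lower, 16 of them in both replicates (camera adjusted p = 0.000136, adjusted p = 0.62 with an estimated correlation), led by Idh3a at -0.49 ± 0.19 and Ogdh at -0.31 ± 0.15. The fatty acid oxidation list fell, with a median of -0.14 and 26 of 31 genes lower (camera adjusted p = 0.00321, adjusted p = 0.62 with an estimated correlation), with Acadm, medium-chain acyl-CoA dehydrogenase, at -0.37 ± 0.15, Cpt2, a carnitine palmitoyltransferase, at -0.57 ± 0.24 and Hadh at -0.55 ± 0.24. Its median was -0.36 in replicate 1 and -0.03 in replicate 2. The ribosomal protein list rose by a median of 0.11, with 34 of 42 genes higher and 29 higher in both replicates (camera adjusted p = 6.46e-05, adjusted p = 0.62 with an estimated correlation), led by Rpl21 at 0.63 ± 0.15 and Rpl23a at 0.32 ± 0.14. Its median was -0.33 without between-array normalization, where that of all probe sets was -0.62. Of these last 3 lists 0 genes passed when adjusted over the list alone, and 0 genes of any list passed over all probe sets.

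Bex1, an adaptor protein best known from neurons, had the smallest p of the genes with late estradiol against sham, at 1.83 ± 0.27 (limma adjusted p = 0.425). It was 3.56-fold higher, at mean log2 signals of 9.80 against 7.97, and without late estradiol replicate 2 it stood at 2.09 and passed (limma adjusted p = 0.0371). The other genes that did not pass were Iqub at 1.68 ± 0.29, Srsf2, a splicing factor, at 0.74 ± 0.17 with its other probe set going the other way, Afm, a vitamin E binding protein, at 3.24 ± 0.76, and Adgrf5 at 0.79 ± 0.19. Lower were Tpgs1 at -4.02 ± 0.74, Col3a1, Fam234a at -1.21 ± 0.25, Loxl1 and Serpinf1 at -1.11 ± 0.27. Nppa stood at 1.29 ± 0.67, but at 2.96 in replicate 1 and -0.38 in replicate 2. Ppargc1a stood at 0.50 ± 0.28, with its other probe set going the other way, Nppb at 0.23 ± 0.17, and Myh6, Myh7 and Atp2a2 at -0.15 ± 0.16, 0.17 ± 0.14 and -0.05 ± 0.14. Gper1 stood at -0.77 ± 1.19. In limma 0 of 18625 probe sets passed and 628 had an unadjusted p under 0.05, against 0 and 1337 with the replicate block, while 86 passed without late estradiol replicate 2. The matrix and TCA calls held when any array was left out, but the TCA call ended with median centring (adjusted p = 0.15) and without between-array normalization (0.523). Without late estradiol replicate 1 the fibroblast and fatty acid oxidation lists had camera adjusted p values of 0.381 and 0.0634. Without sham replicate 1 the fatty acid oxidation, ribosomal and fibroblast lists had 0.614, 0.113 and 0.0714, and without late estradiol replicate 2 the ribosomal list had 0.390.

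With 1 array left out, the matrix median for late estradiol against sham ranged from -0.48 without late estradiol replicate 2 to -0.13 without late estradiol replicate 1, and the fibroblast median from -0.47 without sham replicate 1 to -0.04 without late estradiol replicate 1. The fatty acid oxidation median ranged from -0.35 without sham replicate 2 to -0.08 without sham replicate 1, and the ribosomal median from 0.02 without late estradiol replicate 2 to 0.24 without sham replicate 2. Without normalization the fatty acid oxidation, fibroblast and ribosomal calls ended (adjusted p = 0.34, 0.195 and 0.116), and without the 2 dimmest arrays the fibroblast and fatty acid oxidation calls (0.418 and 0.0988). With the replicate 2 arrays of late estradiol and sham exchanged, fatty acid oxidation genes were called too, at a median of -0.22 (camera adjusted p = 0.000365).

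The mean of both estradiol groups was set against ovariectomy to ask how they differ from it on average, whenever estradiol began. Matrix and fibroblast genes fell, with medians of -0.28 and -0.23 and 43 of 54 and 14 of 16 genes lower (camera adjusted p = 9.78e-07 and 9.38e-05, adjusted p = 0.72 for each with an estimated correlation). Adjusted over the list alone 3 and 2 of their genes passed, with Col3a1 at -1.18, Col1a1 at -0.98 and Col15a1 at -0.85, against 0 over all probe sets. With early estradiol alone the matrix, fibroblast and macrophage medians were 0.01, -0.06 and -0.01, against -0.56, -0.41 and -0.94 with late estradiol, so that these values rest on the late group. The MHC class II list fell, with a median of -0.19 (-0.34 with early and -0.09 with late estradiol) and 16 of 21 genes lower (camera adjusted p = 0.00187, adjusted p = 0.72 with an estimated correlation). Macrophage genes fell, with a median of -0.43 and 17 of 20 lower (camera adjusted p = 0.00407, adjusted p = 0.85 with an estimated correlation), but macrophage medians were 0.11 in replicate 1 and -1.21 in replicate 2. The cell cycle list fell, with a median of -0.34 and 17 of 19 genes lower (camera adjusted p = 0.00407, adjusted p = 0.72 with an estimated correlation), and the circadian clock list rose by 0.21 with 14 of 19 genes higher (camera adjusted p = 0.0296, adjusted p = 0.72 with an estimated correlation). Without ovariectomy replicate 2 the matrix, fibroblast, MHC class II, cell cycle, clock and macrophage lists had camera adjusted p values of 0.381, 0.374, 0.789, 0.789, 0.0676 and 0.252, and the macrophage and MHC class II medians turned to 0.29 and 0.01. Without late estradiol replicate 1 the macrophage and clock lists had 0.413 and 0.167, and without ovariectomy replicate 1 the clock list had 0.446. Without early estradiol replicate 2 the clock, macrophage and cell cycle lists had 0.0564, 0.0705 and 0.0857, and without late estradiol replicate 2 the cell cycle list had 0.0785. With 1 array left out, the largest and smallest medians came without ovariectomy replicate 1 and 2, at -0.46 and -0.15 for matrix, -0.55 and -0.10 for fibroblast, -0.43 and 0.01 for MHC class II, -0.52 and -0.05 for cell cycle, and -1.41 and 0.29 for macrophage genes, and the clock median was 0.08 without ovariectomy replicate 1. The clock call also ended with no intensity trend (adjusted p = 0.0554), the mean of a gene's probe sets (0.109), no normalization (0.0958) and without the 2 dimmest arrays (0.613), the cell cycle call with the filter at the 60th percentile (0.0878), and the MHC class II and fibroblast calls without normalization (0.0958 each). In limma 0 of 18625 probe sets passed here, with 500 at an unadjusted p under 0.05, against 0 and 960 with the replicate block. In the F test over the 4 groups 0 passed and 347 had an unadjusted p under 0.05, against 0 and 860 with the block.

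Single genes of smallest p for both estradiol groups against ovariectomy, none of which passed, were Sinhcaf at 2.64 ± 0.48, Amd1 at 0.72 ± 0.16, Tox at 1.51 ± 0.35, Sppl2a at 0.95 ± 0.24, with 2 of its 3 other probe sets going the other way, and Pawr at 2.13 ± 0.57. Lower, beside Col3a1, Col15a1 and Col1a1, were Fam234a at -0.90 ± 0.21 and Tubb6 at -1.47 ± 0.39. Nppa stood at 0.50 ± 0.58, Ppargc1a at 0.39 ± 0.24, Nppb at 0.15 ± 0.15 and Myh7 at 0.10 ± 0.12. Myh6 stood at -0.04 ± 0.14, Gper1 at -0.24 ± 1.03 and Atp2a2 at -0.01 ± 0.12, with 2 of the 4 other probe sets of Atp2a2 going the other way.

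The comparisons against ovariectomy share its 2 arrays, so their differences correlate by chance. Across 10450 genes, which are not independent replicates, the differences of early and late estradiol from ovariectomy had a correlation of 0.468 and a covariance of 0.113, against 0.540 and 0.101 in 100 simulations of unchanged groups with the spread of the fit with the replicate block. For ovariectomy against sham and early estradiol against ovariectomy the correlation was -0.635 (simulated -0.579) and the covariance -0.129 (simulated -0.101), and for ovariectomy against sham and late estradiol against ovariectomy they were -0.487 (simulated -0.532) and -0.115 (simulated -0.101). The covariances exceeded the simulated ones in size by 0.01 to 0.03. The simulated spread, however, was limma's moderated variance, which is drawn toward a common trend and can lie below the mean variance of the genes. The simulated covariances can therefore be too small, and the excess is no sign of a shared change. The 2 arrays of the shared group were not split between the comparisons, so part of these values may come from its arrays.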

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

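The list tests of late against early estradiol, the estimated correlation, the replicate block and the leaving out of arrays were planned. The exchange of arrays, the matrix values by replicate, the endothelial gap, the differences between pools, the random lists, the count of macrophage genes and the clock gene test were chosen after the results were seen. Each pattern below is a hypothesis from the same 8 arrays that showed it.

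The effects of early and late estradiol, each measured against ovariectomy, differed in 8 gene lists by the direct comparison of late with early estradiol (camera at its preset correlation). The median log2 difference of late minus early was -0.523 for the extracellular matrix list, -0.432 for fibroblast genes, -0.747 for macrophage genes, -0.681 for complement, -0.205 for antioxidant genes, -0.195 for glycolysis, -0.102 for the TCA cycle and 0.0614 for ribosomal proteins. Against ovariectomy the matrix list had a median of 0.01 with early and -0.56 with late estradiol, and complement 0.38 and -0.22. With an estimated correlation none of the 8 was called, the smallest adjusted p being 0.523. The replicate block left 7 called, without the TCA cycle (adjusted p = 0.0588). The matrix, fibroblast, complement and macrophage lists were also called with the replicate 2 arrays exchanged. Start time was not separated from length of exposure or from time since surgery.

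Matrix genes were lower with late estradiol than after ovariectomy alone, with a median of -0.51 in replicate 1 and -0.566 in replicate 2. The dim array with the high Gapdh ratio, late estradiol replicate 1, alone cannot account for the replicate 2 value, which does not contain it and had a 95% interval of -0.71 to -0.36 over 10000 random draws of the genes, with 48 of 54 genes lower. That value rests instead on ovariectomy replicate 2, the pool with the high macrophage genes and the highest actin ratio: relative to sham the matrix means were -0.102 and 0.527 after ovariectomy and -0.59 and -0.209 with late estradiol, in replicates 1 and 2. A smaller share of all cells other than heart muscle cells would lower endothelial genes alike. The endothelial mean instead lay above the matrix mean in both replicates, by 0.603 ± 0.212 in the one with the smaller gap. A loss confined to fibroblasts, whose genes also fell, was not tested by this gap. The error of this gap is a standard error over genes within a pair of arrays, and the 95% interval above also draws genes within a pair of arrays. Neither holds any spread between pools. Differences between pools unrelated to treatment stay open: with the replicate 2 arrays of both groups exchanged, the list had a median of 0.01 and a camera adjusted p of 0.695, but 4 arrays allow only 3 splits into pairs, and the same exchange did call the list for late against early estradiol (-0.185, 0.0184), ovariectomy against sham (-0.213, 0.00339) and early estradiol against ovariectomy (0.166, 3.77e-05). An effect of late estradiol on matrix genes may underlie the pattern, and it cannot be told apart from differences between pools.

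Macrophage genes differed more between the 2 pools of the ovariectomy group, and between those of the late estradiol group, than any 2 group means did. Relative to sham, the group means were 0.86 after ovariectomy, 0.8 with early and -0.06 with late estradiol. Replicate 2 minus replicate 1 had a mean of 0.74 in sham, 1.76 after ovariectomy, 1.15 with late and -0.234 with early estradiol (standard error over 20 genes 0.0681), so a single technical shift between replicate numbers does not account for all of it. Noise of dim genes argues no better, since the median difference of 1.82 between the ovariectomy pools lay at percentile 100 of 10000 random lists of like expression, whose highest was 0.75. More macrophages in that pool of hearts may be the reason, but the count of 20 of 20 genes higher in ovariectomy replicate 2 only restates the difference and decides nothing, so this stays open. The macrophage calls of the report are open to pool differences of any kind, as exchanging the replicate 2 arrays gave a call at an adjusted p of 3.5e-14 between early estradiol and ovariectomy, where the real grouping gave none for this list.

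Clock genes were lower after ovariectomy than after sham surgery, by a median of -0.273 that was -0.067 without ovariectomy replicate 1. Another time of day at harvest could cause this, since clock genes follow the hour, and would move Bmal1, Npas2 and Clock opposite to the genes they drive. Their mean difference was -0.0696 ± 0.108, while 7 genes of the opposite phase had a mean of -0.45 ± 0.10. Both errors are standard errors over genes, which are not independent replicates. These values decide neither way. The labels used here give no harvest time, so an effect of ovariectomy and a shift in harvest time cannot be told apart.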

How the results depend on the processing

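The replicate block, pairing arrays of the same number, called 1 probe set for late estradiol against ovariectomy where the main setting called 0, and ended 2 list calls given in the report. It added calls of the cell cycle list for ovariectomy against sham (camera adjusted p = 0.0494) and of the ribosomal list for both estradiol groups against ovariectomy (0.0471), and changed no other call. For late estradiol against ovariectomy, 1 probe set also passed with 32 added before the log, without a filter, with the filter at the 60th percentile, and with the block and 32 added, which gave 1 in the F test as well. List calls moved from 6 to 10 for ovariectomy against sham and from 5 to 9 for early estradiol against ovariectomy with median centring. For late against early estradiol they moved from 8 to 4 without intensity trend and to 13 with the mean of a gene's probe sets. An estimated correlation and fry gave 0 list calls in every comparison.

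Alternatives added after the data were seen moved list calls too. Without normalization there were 5 for late against early estradiol, 7 and 1 for early and late estradiol against sham, and 3 for both estradiol groups against ovariectomy, and cyclic loess gave 9 for late estradiol against sham. Without the 2 dimmest arrays there were 13 lists and 5 probe sets for ovariectomy against sham, 10 lists for early estradiol against ovariectomy, and 2 probe sets for both estradiol groups against ovariectomy.

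With each array left out in turn, the lone array of a group was assumed to vary like the other groups. Probe sets ranged from 0 to 3 for ovariectomy against sham, 0 to 65 for late estradiol against ovariectomy, 0 to 100 for late against early estradiol, 0 to 86 for late estradiol against sham, 0 to 2 for both estradiol groups against ovariectomy and 0 to 1 in the F test, and were 0 for early estradiol against ovariectomy and sham. Lists ranged from 1 to 13 for ovariectomy against sham, 2 to 10 and 4 to 7 for early and late estradiol against ovariectomy, 5 to 12 for late against early estradiol, 8 to 15 and 2 to 7 for early and late estradiol against sham, and 3 to 8 for both estradiol groups against ovariectomy. The macrophage median ranged from 0.049 to 1.69 for ovariectomy against sham and from -1.41 to 0.292 for both estradiol groups against ovariectomy, and without ovariectomy replicate 2 camera's direction for this list reversed in both. Of 249 results for named genes, 56 had the other direction in at least 1 setting, in 121 of 4664 values. The causes were not tested.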

Other observations

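The list tests and the adjustment over a list alone were planned, and the exchange of arrays was chosen after the results were seen. The lists not described so far gave no camera call in any of the 7 comparisons. The adult sarcomere list, the contractile proteins of the heart muscle cell, had medians between -0.04 and 0.04 in all of them, and the calcium handling and ion channel list between -0.08 and 0.02. The estrogen receptor and responsive gene list had medians of -0.08 after ovariectomy, 0.14 with early and -0.09 with late estradiol against ovariectomy (camera adjusted p = 0.645, 0.188 and 0.847). For late against early estradiol it had -0.18 (camera adjusted p = 0.106), and the cholesterol and lipid synthesis list -0.19 (camera adjusted p = 0.106). The lists of mitochondrial biogenesis, the renin-angiotensin system, heat shock, apoptosis and senescence, protein degradation, growth signalling, skeletal muscle, T and NK cells, and Schwann cells and neurons gave no call either.

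The adipocyte list was not called (median -0.32 for late estradiol against sham, camera adjusted p = 0.0884), but 2 of its genes passed when adjusted over the list alone, against 0 over all probe sets. These were Aqp7, the glycerol channel of fat cells, at -0.93, and Cidea, a lipid droplet protein, at -0.65. Cidea had log2 signals of 9.49 and 9.75 in sham, 9.47 and 9.48 after ovariectomy, 9.13 and 9.10 with early, and 8.94 and 8.99 with late estradiol.

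Plvap, the marker of fenestrated endothelium, passed within the endothelial list for late against early estradiol, at -2.62, and Krt19, a keratin of mesothelium, passed within the mesothelial list for late estradiol against ovariectomy, at -2.76, although neither list was called in that comparison. Plvap had log2 signals of 2.64 and 3.73 in sham, 4.89 and 5.13 after ovariectomy, 5.60 and 5.57 with early, and 2.69 and 3.25 with late estradiol, and was dim throughout.

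The group means of Bex1 rose in the order sham, ovariectomy, early and late estradiol, but in replicate 2 early estradiol lay below ovariectomy, with log2 signals of 7.90 and 8.05, 8.52 and 9.07, 9.41 and 8.89, and 10.07 and 9.53. It was singled out after its values were seen.

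With the replicate 2 arrays of the compared groups exchanged, so that each group held an array of both, camera at its preset correlation called 3, 9, 3, 6, 3 and 1 lists for ovariectomy against sham, early and late estradiol against ovariectomy, late against early estradiol, and early and late estradiol against sham, where the real groups gave 6, 5, 6, 8, 14 and 5. Such groups differ by no treatment on balance, so these counts show how many calls array and pool differences gave here.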
